A study of Mus musculus with 10 samples.

How the data were processed

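Total RNA from whole vagal ganglia of C57BL/6 mice was sequenced in 10 libraries, 5 from animals given vehicle and 5 from animals given lipopolysaccharide (LPS), per the labels. The ganglia were frozen and the RNA was taken up with a column kit for small samples, per the labels' protocols. The submitters' processing notes name TopHat, Cufflinks and Cuffdiff and the mouse genome build mm9. Tool versions, the gene annotation, the strandedness of the libraries and the treatment of reads with several matches are not given in the sources used here. The labels do not say that each library came from a separate animal or pool of animals, so p-values measure the spread between these samples, which may be technical in part.

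The deposited table holds 23309 genes for each of the 10 libraries, with columns that follow Cuffdiff's table of values per replicate, per the file headers. Its first measure is the fragments assigned to each gene, an estimated count deposited without scaling. Of these values 98.3% were whole within a tolerance of 1e-06, and 865 genes had a value that was not whole in at least 1 library. A second deposited measure, a scaled signal, equals the estimated counts divided by 1 size factor per library from the authors' Cuffdiff run. The third is FPKM (fragments scaled to transcript length and library depth), deposited by the authors after the same scaling. The table names the treatment and numbers the libraries of each group from 0, while the labels number them from 1. The groups are therefore certain, and the number within a group was read as shifted by 1.

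The file marks 6 genes as having too many fragments to be estimated and lists them at 0. Lars2, Rn45s, Tuba1a and Ubb carried this mark in all 10 libraries and Map1b in the 5 vehicle libraries, so a 0 for Map1b is a failed estimate. A further 13 genes carried a failure mark in at least 1 library. These 19 genes were left out, and 23290 remained, of which 1891 were at 0 in all 10 libraries.

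Because the file holds estimated counts, these were rounded to whole numbers and tested with edgeR 4.0.16 (quasi-likelihood test, TMM normalization, filterByExpr with default settings) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all 14584 genes tested. The design, written before the data were examined, gave limma with trend for FPKM and edgeR for counts. Genes past the threshold had an adjusted p under 0.05. Log2 fold changes are LPS over vehicle, with standard errors (SE) derived from the fold change and the F statistic. Levels are given as CPM (fragments scaled to library size) with the SD over 5 libraries, and list scores as the mean over a list of log2 CPM (prior count 2) centred on each gene's mean. The test was run on simulated data made from the means, library sizes and dispersions of this comparison, with 200 changed genes among the 14389 that passed the filter. It recovered 60% of the 100 genes changed 2-fold and 93% of the 100 changed 4-fold, and 3.2% of its 158 calls were false. The changed genes were drawn only from genes above a minimum mean CPM, so the recovery does not cover genes of low level. Each gene was simulated independently of the others, so the share of false calls does not cover genes that vary together.

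The 36 gene lists were fixed before the data were examined. The 34 with at least 3 tested genes were compared with all other genes by camera (limma 3.58.1, preset correlation of 0.01), with Benjamini-Hochberg adjustment over the lists, and again with a correlation estimated for each list. Each list score was also compared between groups by an exact permutation test over the 252 labelled splits of the 10 libraries, 2-sided, whose smallest possible p is 0.00794. Lists at that permutation p had an adjusted p of 0.045 (Benjamini-Hochberg over the lists). For 6 lists the median, the mean and the camera direction differed in sign, and none of these was past the threshold. They are the lists of NF-kB targets, Toll-like receptor 4 components, ion channels, Schwann cell, red blood cell and skeletal muscle markers. The genes named in the text are the 10 largest increases and 10 largest decreases past the threshold, 18 of 19 genes chosen in advance, and up to 4 members per list with the smallest adjusted p under 0.05. Any other gene is said to have been chosen after its values were seen.

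Library totals ran from 13492848 to 32327915 fragments in the vehicle group and from 17108381 to 21635462 in the LPS group. A floor of 3 fragments over a group corresponds to 0.0239 CPM in the vehicle group and 0.0324 CPM in the LPS group, which covers counting error only. No pair of libraries within a group agreed within sampling noise; the lowest chi-square per degree of freedom was 12.9. Alternatives were other filters, normalizations and tests (including DESeq2 1.42.0 and limma on log2 FPKM with pseudocounts of 0.1, 0.5 and 1), the replicate number as a block, each library left out in turn, other thresholds and other list tests. Transcript length and GC content for 1 check came from GENCODE release M21 transcripts matched by symbol, which covered 93.9% of tested genes; no coordinates were used because that annotation is for another build. Genes of multigene families, among them the Gbp, Irgm, Tgtp, H2 and ribosomal protein genes, can share reads with close copies, and their values are uncertain to that extent.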

Results

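RNA sequencing measured transcript levels in whole vagal ganglia, the clusters of sensory nerve cell bodies whose axons run in the vagus nerve to the airways and other organs, together with their glia, vessels and connective tissue. Mice of the C57BL/6 strain received vehicle (5 libraries) or LPS (5 libraries), a bacterial outer membrane component that provokes inflammation of the lung. Dose, route and time after treatment are not given in the sources used here. The vehicle libraries held 13492848, 25522819, 32327915, 26618756 and 28594691 fragments and the LPS libraries 17943270, 17399861, 19690689, 17108381 and 21635462. Between 17303 and 18198 genes had a fragment in a library, and the 10 most abundant genes took 4.94% to 6.25% of the fragments. On the first principal component (21.1% of the variance) vehicle libraries lay at -37.7 to -13.3 and LPS libraries at 1.4 to 73.3. LPS replicate 5 was the highest and had the lowest mean correlation with its own group (0.934). LPS replicates 2 and 4 correlated slightly more with the vehicle group (0.96 and 0.956) than with their own (0.957 and 0.954), unlike every other library.

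The comparison of LPS with vehicle asked which transcripts of the vagal ganglia differ with lung inflammation, and the series title names a nerve injury programme in sensory neurons. Atf3, a transcription factor induced in axotomized neurons, rose 5.29-fold, from 8.64 ± 2.35 CPM in vehicle to 45.4 ± 10.9 CPM in LPS (SD, n = 5 each; log2 fold change 2.40 ± 0.21 SE, edgeR adjusted p = 0.00012). The interferon-inducible GTPase genes Igtp and Iigp1, the endothelial adhesion molecule genes Vcam1 and Sele and the acute-phase gene Lcn2 also rose. The collagen genes Col1a1 and Col3a1 and the satellite glial cell genes Fabp7 and Ednrb fell. In all, 122 genes were higher and 92 lower in LPS among 14584 tested, and 60 and 37 of them changed at least 2-fold. The groups did not overlap for 602 of all tested genes (4.13%), where chance gives 0.794%. When 1 library was left out the counts ran from 65 to 133 higher and from 31 to 87 lower, with 65 and 31 without LPS replicate 1. DESeq2 called 302 higher and 273 lower.

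The largest increase was in Cxcl13, a chemokine that attracts B cells, with a log2 fold change of 4.88 ± 0.70 (11 fragments in all vehicle libraries and 263 in all LPS libraries). Lrg1, a secreted acute-phase glycoprotein, had one of 4.80 ± 0.54. Lcn2, an iron-sequestering protein of the acute phase, rose from 0.638 ± 0.464 to 12.9 ± 6.82 CPM. Tgtp2 (4.26) and Gm12250 (3.03) encode interferon-inducible GTPases, Sele (3.14) the adhesion molecule E-selectin, Plin4 (3.71) a lipid droplet protein and Chi3l3 (4.32) a chitinase-like protein of macrophages. Ccdc67 (4.38) and Gm16548 (3.46) completed the 10. Removing 1 library moved the log2 fold change most for Lrg1 (4.46 to 5.44, the highest without vehicle replicate 4), Ccdc67 (4.09 to 5.27, the highest without vehicle replicate 5) and Plin4 (2.97 to 4.11, the lowest without LPS replicate 4) among those of the 10 whose call stayed. The call was lost without any 1 of 4 libraries for Chi3l3 (vehicle replicates 2 and 5, LPS replicates 1 and 5; log2 fold change 3.80 to 4.82 over all removals, adjusted p up to 0.0767) and any 1 of 3 for Gm16548 (vehicle replicates 3, 4 and 5; 3.18 to 4.00, adjusted p up to 0.0577).

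The nerve injury and axon regeneration list had 34 tested members, of which 6 rose and 0 fell (7 rose when adjusted over the list alone). Besides Atf3, these were Gpr151, a receptor induced in injured sensory neurons (2.42 ± 0.29), Serpinb1a (1.06 ± 0.14), Flrt3, a membrane protein of axon guidance (0.98 ± 0.11), Sox11, a transcription factor of axon growth (0.84 ± 0.16), and Gadd45a (0.93 ± 0.15, chosen after its value was seen). Other genes of that response did not pass the test. Sprr1a had a log2 fold change of 0.57 ± 0.62, Jun of 0.47 ± 0.25, Gal of -0.21 ± 0.18 and Gap43, already abundant at 668 ± 36.8 CPM in vehicle, of -0.12 ± 0.06. Npy had -2.63 ± 1.42 and was at 169 CPM in vehicle replicate 4, where sympathetic markers were also highest. The Npy log2 fold change ran from -3.31 to -0.02 over all removals of 1 library. The list ranked above other genes (camera adjusted p = 2.67e-08) and did so with an estimated correlation (adjusted p = 0.0049), and its score was higher in 5 of 5 LPS libraries than in any vehicle library (difference 0.321, exact permutation p = 0.00794). The call of Sox11 was lost without LPS replicate 1 or LPS replicate 2 (log2 fold change 0.77 to 0.93 over all removals, adjusted p up to 0.054).

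**Figure D1:**
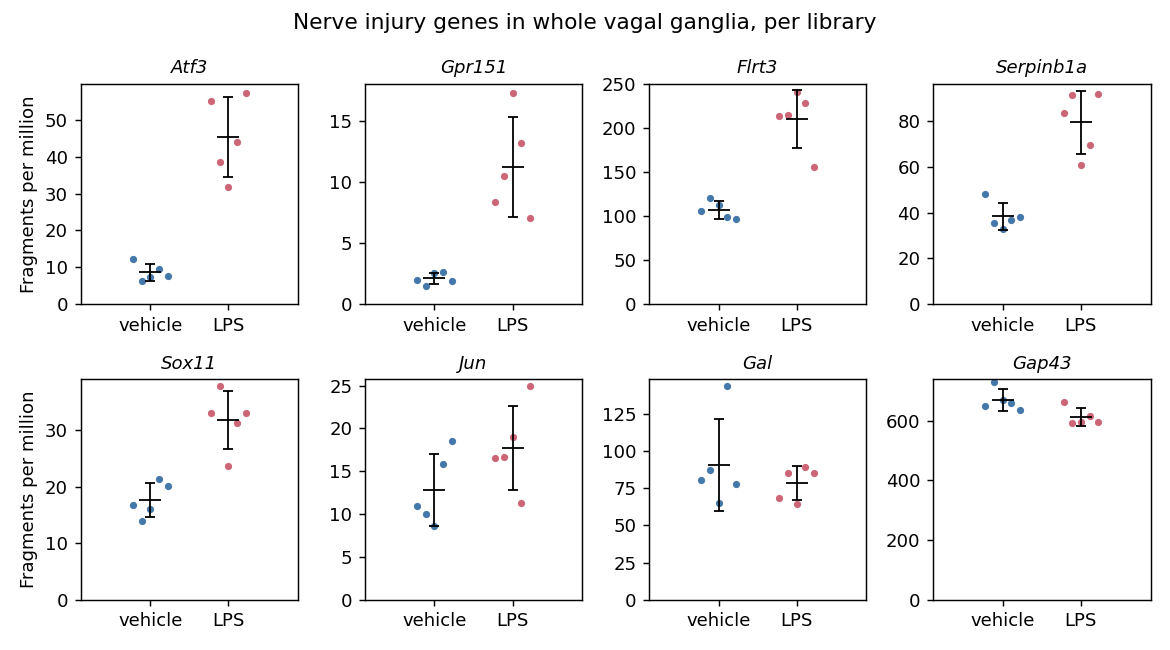
CPM (linear axis from 0) of 8 nerve injury genes in each vehicle library (blue, n = 5) and LPS library (red, n = 5); the bar and whiskers are the mean and SD. Atf3 lay at 45.4 ± 10.9 in LPS against 8.64 ± 2.35 in vehicle, while Gal and Gap43 overlapped between groups.

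Of 49 tested interferon-stimulated genes, 16 rose and 0 fell (24 adjusted over the list alone). The immunity-related GTPases Igtp (1.46 ± 0.12) and Iigp1 (2.38 ± 0.25), the guanylate-binding protein gene Gbp2 (2.08 ± 0.19) and the immunoproteasome subunit gene Psmb8 (1.06 ± 0.13) had the smallest adjusted p. Among members chosen after their values were seen, Isg15 (0.09 ± 0.23), Ifit1 (0.16 ± 0.12), Rsad2 (-0.03 ± 0.25) and Usp18 (-0.01 ± 0.18) did not pass. Chosen likewise, Zbp1 (2.01 ± 0.54), Ifi44 (1.39 ± 0.44), Bst2 (0.63 ± 0.16), Ifitm3 (0.51 ± 0.15) and Oasl2 (0.29 ± 0.09) passed over the list alone. Cxcl10 had 0.08 ± 0.43. The list was past the threshold with the preset and the estimated correlation (adjusted p = 5.82e-36 and adjusted p = 0.00923). The MHC class I presentation list, which shares Psmb8, Psmb9 and Tap1 with it, had 4 of 20 members rise and 0 fall (12 adjusted over the list alone). Tap1, the peptide transporter, had 1.65 ± 0.26, Psmb9 1.28 ± 0.18 and the nonclassical class I gene H2-T23 0.81 ± 0.13 (adjusted p = 1.28e-15 with the preset and 0.00738 with the estimated correlation).

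Endothelial activation genes rose in 6 of 18 tested members and fell in 0 (11 up and 1 down adjusted over the list alone). Vcam1, which binds leukocytes on inflamed vessels, went from 15.2 ± 5.24 to 52.9 ± 13.6 CPM, and Ch25h, an oxysterol-producing enzyme, had 2.55 ± 0.42. Lrg1 and Sele belong to this list too, and it was past the threshold with the preset (adjusted p = 8.13e-14) and the estimated correlation (adjusted p = 0.00738). Of 15 tested endothelial cell markers, 2 rose (Ly6c1, 1.30 ± 0.20, and Slco1a4, 0.83 ± 0.19) and 0 fell (4 rose over the list alone), with a list adjusted p of 0.00161 but adjusted p = 0.363 with an estimated correlation and 0.0734 without LPS replicate 5. The score of these markers had an exact permutation p of 0.175 (0.349 adjusted over the lists). The acute-phase and IL-6/STAT3 list had 3 of 26 members rise (5 adjusted over the list alone): Lrg1, Lcn2 and Serpina3n (0.48 ± 0.09). Its camera adjusted p was 4.51e-05, and adjusted p = 0.0871 with an estimated correlation. The score of the acute-phase list had an exact permutation p of 0.0159 (0.0675 adjusted over the lists). The Serpina3n call was lost without vehicle replicate 5 (adjusted p up to 0.0509, log2 fold change 0.43 to 0.53 over all removals), and that of Slco1a4 without any 1 library but vehicle replicate 3 (0.69 to 0.93, adjusted p up to 0.0929).

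Glucocorticoid-induced genes rose in 6 of 24 members and fell in 0 (13 adjusted over the list alone). They included Lcn2, Plin4, the sulfotransferase gene Sult1a1 (0.95 ± 0.19) and Fkbp5, a chaperone of the glucocorticoid receptor (0.71 ± 0.16). The list adjusted p was 2.77e-13, and adjusted p = 0.134 with an estimated correlation, while its score separated the groups fully (difference 0.854, exact permutation p = 0.00794). Removing a single library ended the call of Sult1a1 for vehicle replicates 1, 2 and 3 and LPS replicates 3 and 4 (0.82 to 1.07, adjusted p up to 0.0714) and of Fkbp5 for each but vehicle replicate 4 (0.61 to 0.80, adjusted p up to 0.0955).

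Of 22 tested NF-kB targets, cytokines and chemokines, Cxcl13 and Il18bp, a decoy for IL-18 (2.32 ± 0.39), rose and Ccl11, an eosinophil chemokine (-1.57 ± 0.36), fell; 2 rose and 2 fell over the list alone, and the list did not pass (adjusted p = 0.749). The Ccl11 call was lost without any 1 library but LPS replicate 4 (-2.14 to -1.41, adjusted p up to 0.119). Il6, Tnf and Il1b had 77, 39 and 6 fragments in all 10 libraries together and fell below the filter. Fitted with no filter they had log2 fold changes of 0.64 ± 0.97, 3.68 ± 1.75 and 1.96 ± 1.48 and did not pass (adjusted p = 0.829, 0.417 and 0.598). Of 10 tested neutrophil markers, 1 rose, Lcn2, which is also in the acute-phase and glucocorticoid lists (5 rose over the list alone). S100a8, chosen after its values were seen, was at 8.43, 11.4 and 42.4 CPM in LPS replicates 3, 4 and 5 but at 2.89 and 1.18 in LPS replicates 1 and 2, against 0.127 to 2.67 in vehicle. The neutrophil list had an adjusted p of 3.34e-08, and adjusted p = 0.136 with an estimated correlation. Its score had an exact permutation p of 0.0714 (0.202 adjusted over the lists). Among 28 macrophage and monocyte markers Ly6c1, which is also in the endothelial cell list, rose. Pf4, a chemokine of resident macrophages and platelets, fell (-1.77 ± 0.38). Over the macrophage list alone 2 rose and 1 fell, and the list adjusted p was 0.397. In the complement list 1 of 18 genes rose, C4b (1.00 ± 0.21; 1 up and 1 down over the list alone; list adjusted p = 0.749). The Pf4 call was lost without any 1 library but vehicle replicate 2 and LPS replicates 4 and 5 (-1.99 to -1.59, adjusted p up to 0.0979). The C4b call was lost without any 1 but vehicle replicate 4 and LPS replicate 5 (0.81 to 1.12, adjusted p up to 0.0724).

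Genes of fibroblasts and extracellular matrix fell in 6 of 20 members and rose in 0 (13 fell adjusted over the list alone). Lum, which encodes the proteoglycan lumican, fell from 184 ± 67.6 to 34.0 ± 15.9 CPM and Col3a1 from 102 ± 64.2 to 14.5 ± 7.33, and Col1a1 had a log2 fold change of -2.36 ± 0.38. Postn, the matrix protein periostin, had -2.97 ± 0.43. The largest decreases also held Mfap4, a microfibril protein (-6.78 ± 0.96, from 723 vehicle and 5 LPS fragments, and -6.26 to -8.47 over all removals of 1 library, the last without LPS replicate 4), Col8a2 (-3.42 ± 0.61), Sfrp4, a secreted Wnt antagonist (-2.93 ± 0.57), Angptl1 (-2.42 ± 0.43), Tnfrsf11b, the decoy receptor osteoprotegerin (-4.44 ± 0.94), Retnla (-3.67 ± 0.82) and Lypd2 (-2.85 ± 0.64). The list adjusted p was 1.09e-16, and adjusted p = 0.0863 with an estimated correlation, and its score was lower in every LPS library than in every vehicle library (difference -1.418, exact permutation p = 0.00794). Vehicle replicates 1, 4 and 5, with the highest matrix scores (1.13, 1.35 and 1.07, against -0.06 and 0.06 in vehicle replicates 2 and 3), also had the highest sympathetic marker scores of their group (0.76, 2.49 and -0.16). Between the groups the scores parted. LPS replicates 3, 4 and 5 had sympathetic scores of -0.10, 0.12 and 0.40, above vehicle replicate 5, but matrix scores of -0.38, -0.29 and -0.39. LPS replicates 1 and 2 were the lowest of their group in both (sympathetic -1.06 and -0.78, matrix -1.50 and -0.99). The call of Tnfrsf11b was lost without vehicle replicate 1, 4 or 5 or LPS replicate 1 or 3 (-5.47 to -4.09, adjusted p up to 0.0887), and that of Sfrp4 without vehicle replicate 5 or LPS replicate 1, 2 or 5 (-3.21 to -2.60, up to 0.0656). Retnla lost it without any 1 library but vehicle replicates 2 and 3 and LPS replicate 5 (-4.12 to -3.26, up to 0.119), and Lypd2 without any 1 but vehicle replicate 3 and LPS replicates 1 and 3 (-3.51 to -2.53, up to 0.108).

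Of 15 markers of satellite glial cells, which wrap sensory neuron cell bodies, 3 fell and 0 rose (5 fell over the list alone). Of their values 9 were lower and 6 higher. Fabp7, a fatty acid-binding protein, went from 525 ± 40.0 to 271 ± 32.6 CPM, the endothelin receptor gene Ednrb from 351 ± 23.4 to 205 ± 29.8 and the potassium channel gene Kcnj10 from 47.5 ± 6.12 to 29.8 ± 3.35. Each was lower in all 5 LPS libraries than in any vehicle library. The list adjusted p was 1.4e-05, and adjusted p = 0.0951 with an estimated correlation. The list score overlapped between the groups (difference -0.235, exact permutation p = 0.0317, and 0.12 adjusted over the lists). Of 17 Schwann cell and myelin markers 0 passed in edgeR, 2 had an unadjusted p under 0.05 and DESeq2 called 0 (list adjusted p = 0.749).

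Neuronal identity and excitability genes gave almost no calls. Of 31 vagal sensory neuron identity genes 0 passed in edgeR, 6 had an unadjusted p under 0.05 and DESeq2 called 1 (list adjusted p = 0.546). Of 45 ion channel and receptor genes 1 rose, the neuropeptide Y receptor gene Npy1r (1.08 ± 0.24; 1 over the list alone; list adjusted p = 0.749), and its call was lost without any 1 library but LPS replicate 4 (0.92 to 1.22, adjusted p up to 0.114). The channels Trpa1 (0.15 ± 0.14), Trpv1 (0.01 ± 0.15), P2rx3 (0.23 ± 0.09) and Scn10a (-0.26 ± 0.09) did not pass. P2rx3 did without LPS replicate 5 (0.31, adjusted p = 0.0473). With all libraries P2rx3 was above every vehicle library in 4 LPS libraries and below every one in 1 (edgeR unadjusted p = 0.0276, adjusted p = 0.281). Scn10a was lower in all 5 LPS libraries than in any vehicle library (edgeR unadjusted p = 0.0129, adjusted p = 0.208), where 4.13% of all tested genes had groups that did not overlap. Of 19 neuropeptide genes 0 passed in edgeR, 3 had an unadjusted p under 0.05 and DESeq2 called 1 (list adjusted p = 0.0746, and 0.0246 without vehicle replicate 2), with Calca at 0.20 ± 0.20 and Tac1 at 0.32 ± 0.15.

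**Figure D2:**
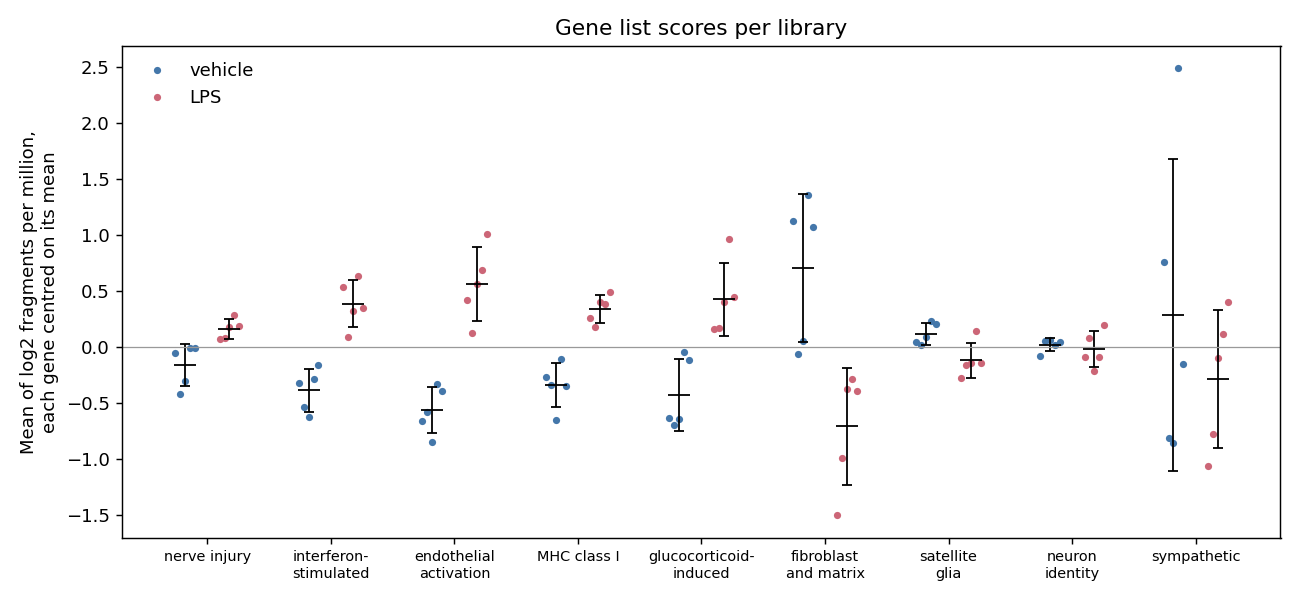
Score of 9 gene lists (mean of log2 CPM, each gene centred on its mean over the 10 libraries) in each vehicle library (blue, n = 5) and LPS library (red, n = 5); the bar and whiskers are the mean and SD. The nerve injury, interferon, endothelial activation, MHC class I, glucocorticoid and matrix scores separated the groups fully, while neuron identity scores overlapped and vehicle replicate 4 stood at 2.49 for sympathetic markers.

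Among other processes, Rbm3 (1.65 ± 0.16) and Cirbp (1.17 ± 0.15), RNA-binding proteins induced by mild cold, rose within the heat shock and unfolded protein response list, while the chaperone genes Hsph1 (-0.63 ± 0.08), Hspd1 (-0.29 ± 0.06) and Hsp90b1 (-0.27 ± 0.06, chosen after its value was seen) fell. The 24 members gave the same numbers over the list alone, 2 up and 3 down, and the list did not pass (adjusted p = 0.505). Cholesterol synthesis genes held 3 decreases, Cyp51 (-0.28 ± 0.06), Mvd (-0.46 ± 0.10) and Dhcr7 (-0.37 ± 0.08), and 1 increase, Lss (0.61 ± 0.13), in 21 members (8 down and 1 up over the list alone). Its adjusted p was 0.000218, and adjusted p = 0.363 with an estimated correlation. The score of the cholesterol list had an exact permutation p of 0.167 (0.349 adjusted over the lists). Nr1d1, a repressor of the circadian clock, was the single decrease (-0.72 ± 0.13) among 18 clock genes (3 over the list alone; list adjusted p = 0.0498, and adjusted p = 0.363 with an estimated correlation). The lists of 16 cell cycle genes and 29 oxidative phosphorylation genes passed (adjusted p = 0.0336 and 0.0064) with 0 single genes past the edgeR threshold (4 and 7 at an unadjusted p under 0.05, and 1 in each called by DESeq2) and lost the call with an estimated correlation (adjusted p = 0.121 and adjusted p = 0.669). These list calls were also lost without single libraries: cell cycle without vehicle replicate 2, 3 or 5 or LPS replicate 1, 3, 4 or 5 (adjusted p up to 0.148), oxidative phosphorylation without vehicle replicate 4 or LPS replicate 1 (0.113 and 0.0848) and clock without vehicle replicate 4 or 5 or LPS replicate 1, 2, 3 or 5 (up to 0.139). The scores of the cell cycle, oxidative phosphorylation and clock lists had exact permutation p-values of 0.0159, 0.143 and 0.0794. Adjusted over the lists these were 0.0675, 0.347 and 0.208. The Cyp51 call was lost without any 1 library, those of Hspd1 and Dhcr7 without any but vehicle replicate 5, that of Mvd without any but LPS replicate 3 and that of Lss without any but vehicle replicate 3 and LPS replicate 5 (adjusted p up to 0.112).

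Of 21 immediate early genes 1 rose, Atf3 (1 up and 1 down over the list alone; list adjusted p = 0.117). Besides the neuron identity and Schwann cell lists, those with 0 members past the edgeR threshold and a list adjusted p of 0.104 or more were Toll-like receptor 4 components (20 genes, 0.951), MHC class II (13, 0.488), T, NK and B cells (3, 0.923), pericytes and smooth muscle (11, 0.104), red blood cells (6, 0.955), skeletal muscle (9, 0.972), adipocytes (10, 0.108), sympathetic ganglion and carotid body (10, 0.142), central glia (7, 0.109), cartilage and bone (5, 0.227) and hypoxia and glycolysis (19, 0.505). Without single libraries 3 of these lists passed. Pericytes and smooth muscle did so, lower in LPS, without vehicle replicate 2 or LPS replicate 5 (camera adjusted p = 0.0184 and 0.0276). Adipocytes did so, higher in LPS, without vehicle replicate 2 or LPS replicate 1 or 4 (0.0431, 0.00564 and 0.00259). The adipocyte score was 1.93 and 2.57 in LPS replicates 3 and 5 but -1.53, -0.165 and -1.95 in LPS replicates 1, 2 and 4, against -1.45 to 0.71 in vehicle. Sympathetic ganglion and carotid body did so, lower in LPS, without vehicle replicate 2, 3 or 5 (0.0354, 0.0354 and 0.0284). Of the 113 tested members of these 11 lists, 18 had an unadjusted p under 0.05 and DESeq2 called 0; over all genes 1987 had an unadjusted p under 0.05. Mast cell markers (2 tested) and sex-linked genes (1 tested) were too few for a list test. Xist was at 35.0 to 61.2 CPM in all 10 libraries, and 4 Y-linked genes held 6 fragments in total.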

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

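All checks of single libraries here were planned by rule, and their threshold marks about 1 in 20 groups by chance; 212 group values were checked and 6 stood apart, where chance gives about 10.6. The red blood cell marker score was -1.14 in vehicle replicate 3 against 0.0781 to 0.523 in the other vehicle libraries, and -2.25 in LPS replicate 2 against 0.153 to 0.916 in the other LPS libraries. Chi3l3 was at 0.353 CPM in LPS replicate 2 and at 5.32 to 14.2 CPM in the other LPS libraries. Plin4 was at 34.4 CPM in LPS replicate 4, above the 6.36 to 9.19 CPM of the others, and Fkbp5 was highest in the same library at 29.2 CPM against 19.6 to 21.9 CPM. Flrt3 was at 155 CPM in LPS replicate 5, below the 213 to 240 CPM of the other LPS libraries and above every vehicle library.

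Among genes below the filter, Tnf had 36 fragments in LPS replicate 5 and 0 to 2 in each other library, so its signal came from 1 LPS library and lay above the vehicle libraries beyond counting error.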

How the results depend on the processing

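The FPKM fit with pseudocount 1, the Cuffdiff size factors, the fit that kept genes with a failure mark, thinning, the removal of vehicle replicate 4 with LPS replicate 5 and the sympathetic covariate were chosen after seeing the data. Of the 214 genes called in the reported fit, those tested again in each of the 27 other fits (205 to 214) kept their sign, and the median of all genes stayed within 0.02 of 0. The nerve injury list kept its call under all 28 alternatives (median 0.21 to 0.29, adjusted p 1.98e-09 to 0.0049), as did the interferon, endothelial activation and MHC class I lists. Against 122 higher and 92 lower, the counts were 302 and 273 with DESeq2, 211 and 148 with array weights, 233 and 188 at an adjusted p under 0.1, 60 and 37 with at least a 2-fold change, and 81 and 43 without vehicle replicate 4 and LPS replicate 5; higher genes numbered 188 and 193 with FPKM and pseudocounts of 0.5 and 1. The 2-fold rule keeps a subset of the same calls and the removals use fewer libraries; otherwise the cause was not tested. Leaving out 1 library gave 65 to 133 higher and 31 to 87 lower genes. The counts moved over 1.5-fold without vehicle replicate 1 (51 lower), 3 (71 higher, 61 lower), 4 (68, 31) and 5 (66, 33) and without LPS replicate 1 (65, 31), 2 (78, 42), 3 (71, 56) and 4 (75 higher). Of 57 called named genes 37 kept the call in every single removal and 15 lost it in at least 5. Without vehicle replicate 4 and LPS replicate 5, 17 of the 55 with a value lost the call. With the replicate block 13 of 57 lost it, with array weights 7, with the covariate 6 and in each other fit of all libraries at most 3. The libraries sharing a number did not deviate together (correlations -0.053 to 0.096, and 2 of 10 libraries correlated best with their own number); with the replicate number as a block 84 genes were higher and 67 lower. With an estimated correlation 4 lists passed instead of 14, and with fry, a rotation test of each list by itself, 10 passed. Those 10 included the neuropeptide list (fry adjusted p = 0.0463), which the reported test did not call. They left out the neutrophil, endothelial cell, cholesterol, oxidative phosphorylation and clock lists, which it did. Of 948 list values under alternatives 49 lost the call (clock 16, cell cycle 15, oxidative phosphorylation 6, endothelial cells 4, neutrophils 2, cholesterol 2, and acute-phase, glucocorticoid, satellite glia and matrix 1 each). A call was gained by 19 (pericytes 6, neuropeptides 4, adipocytes 4, sympathetic 3, macrophages 1 and immediate early genes 1). All sign changes were in values past no threshold, and their cause was not tested. Toll-like receptor 4 median: -0.03, -0.03 and -0.02 with FPKM and pseudocounts 0.1, 0.5 and 1, -0.02 with the block, -0.06 with array weights, -0.01 without vehicle replicate 4 and LPS replicate 5, and -0.04 to 0.06 over single removals. Ion channels: 0.02, 0.01 and 0.01 with FPKM, 0.01 with a mean CPM filter, thinning or the covariate, 0.00 with DESeq2 size factors, 0.02 with upper-quartile or quantile scaling or the block, 0.03 with array weights, and -0.07 to 0.06 over removals. Schwann cells: -0.02 with pseudocount 0.1, -0.09 with array weights, 0.00 without that pair, and -0.15 to 0.14. Complement: 0.02, 0.01 and 0.01 with FPKM, 0.02 without that pair, 0.08 with the covariate, and -0.14 to 0.06. Skeletal muscle: -0.14, -0.07 and -0.04 with FPKM, -0.34 with no filter or the mean CPM filter, -0.06 with quantile scaling, -0.22 with the block, -0.19 with the covariate, and -0.18 to 0.18. NF-kB targets: 0.01 and 0.02 with pseudocounts 0.5 and 1, 0.03 with no filter, 0.21 with the mean CPM filter, and -0.18 to 0.04. T, NK and B cells: 0.25 with the block, and -0.36 to 0.44. With array weights neuron identity was 0.00 (-0.06 to 0.02 over removals), macrophages -0.02 (-0.11 to 0.39), red blood cells -0.39 (0.00 to 0.32) and adipocytes -0.14. Immediate early genes were at -0.03 without that pair (-0.08 to 0.25), and hypoxia genes at -0.08 to 0.02. Cxcl10 was at -0.05 without that pair and -0.16 with the covariate (-0.16 to 0.27 over removals), Npy at 1.22 and Trpv1 at -0.08 with the covariate (Trpv1 -0.08 to 0.11), and Gal at -0.31 to 0.02.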

Other observations

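The tests of the neuron share, the immediate early genes, the connective tissue, the neck tissue (with the removal of vehicle replicates 1, 4 and 5), the splits with an estimated correlation and the chaperones were chosen after the results they bear on were seen, and the groups in this part were picked after their values were seen. Ribosomal protein genes rose in 21 of 81 tested members and fell in 0, with a median log2 fold change of 0.25 and 80 members above 0. Rps3 had 0.42, Rpl32 0.40 and Rps18 0.41, and Eef1a1, the translation elongation factor, 0.34. The genes Fasn (-0.58), Scd1 (-0.61), Elovl6 (-0.47) and Elovl5 (-0.43) of fatty acid synthesis and Acsbg1 (-0.71), a lipid-activating enzyme, were lower. No list of such genes was tested. Higher genes outside the fixed lists included the interferon-inducible GTPase genes Ifi47 (2.78), Gbp9 (1.59) and Gm4951 (1.74) and the surface antigen gene Ly6a (1.44). The basement membrane genes Nid1 (-0.99) and Nid2 (-1.90) were lower. The score of 20 heat shock chaperones, tested first, differed by -0.16 (exact permutation p = 0.0397), and that of the 11 outside the fixed list by -0.16 (exact permutation p = 0.00794).

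For the number of genes past the threshold 1 of 100 splits of the 10 libraries into 5 and 5, the real one, gave as many as 214. The highest other split gave 3. These values argue against chance, although 1 of 100 is the smallest share that these splits could give. They cannot tell the treatment from any other difference between the groups. For the number of lists past the threshold with the preset correlation chance cannot be excluded, since 22 of 100 splits gave at least the 14 of the real split and the highest other gave 23. With an estimated correlation, counted after that result was seen, 1 of 100 splits, the real one, gave as many as 4 lists, and the highest other gave 1.

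The rise of nerve injury genes was weighed against a larger share of neurons and against handling of the tissue. A larger share of neurons would raise neuron identity genes alike, yet the injury score rose by 0.36 more than the identity score (exact permutation p = 0.0317), and the identity score itself differed by -0.04. Handling or dissection stress stays open: without the 2 genes in both lists, Atf3 and Jun, the score of 32 injury genes exceeded that of 19 immediate early genes by 0.34, with an exact permutation p of 0.0635, and those genes went both ways. A neuronal response to LPS may account for the pattern, as a hypothesis, and the ganglion cells that hold these transcripts were not separated here.

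The fall of collagen and matrix genes was weighed against tissue composition. With the sympathetic marker score as a covariate the median of the matrix list was -1.17, which argues against neighbouring neck tissue with these markers as the whole cause. Its score differed by -1.06 without vehicle replicates 1 and 4 (exact permutation p = 0.0179, the smallest that 56 splits can give) and by -0.71, against -1.42 with all libraries, without vehicle replicates 1, 4 and 5, where the 2 vehicle libraries left still lay above every LPS library (p = 0.0952, since 1 other of 21 splits, with the 2 lowest LPS libraries set apart, gave a larger difference), so such tissue stays open as part of the cause. Less connective tissue in the LPS dissections may account for part, since the score of 29 fibroblast identity genes differed by -0.79 (exact permutation p = 0.0476), and it stays open as the whole cause: 34 collagen and matrix genes, 21 of these and the 12 of the fixed list fell further (by -0.57, -0.33 and -0.89; exact permutation p = 0.00794 in each), but these were set apart from the identity genes after the fall was seen, with 6 calls in the 12 and 0 in the 29 (medians -1.84 and -0.66, and 6 of the 29 values above 0). Whether LPS lowered matrix transcription in the remaining fibroblasts was not tested.

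The rise of ribosomal protein genes was weighed against a bias of transcript length, GC content or expression level. Genes matched on these, 10 per ribosomal protein gene, had a median log2 fold change of 0.07. Of these 410 genes 293 had higher values, 8 rose and 0 fell, and their score differed by 0.09 (exact permutation p = 0.0635). The ribosomal protein score rose by 0.18 more than theirs (exact permutation p = 0.00794). The ribosomal protein genes were picked after their rise was seen, so that p-value cannot decide whether such a bias was the whole cause. The matched genes rose less, and such a bias stays open as part of the cause. How close the matches were was not measured. Reads shared with the many ribosomal protein pseudogenes stay open, because the counting of such reads is not given in the sources used here. An effect of LPS on these transcripts was not tested apart from these.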
